A study of Mus musculus with 12 samples.

How the data were processed

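RNA sequencing was carried out on primary mouse embryonic fibroblasts of 4 genotypes, wild type (WT), Blm knockout (KO), Recql KO and double KO, with 3 libraries per genotype and 12 in total. Per the labels' protocols, cells were grown in 3% O2 and 5% CO2 with 10% fetal bovine serum, polyadenylated RNA was used and libraries were made with a KAPA stranded mRNA kit. Per the submitters' processing notes, reads were processed with Bowtie2 2.1.0, a short-read aligner, and RSEM 1.2.15, a program that shares out reads among transcripts, with the mouse genome build mm10. The authors deposited 1 table of expected counts per gene, the estimated counts that RSEM gives, which need not be whole when a read could come from several genes. Between 17.4% and 20.2% of the values in a library were not whole. The annotation version, the strand setting of the counting, the read length and any filter on reads were not given in the sources used here.

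Expected counts were rounded to whole numbers and tested in R 4.3.3. The table held 24054 genes. edgeR 4.0.16 was used with its filter for low counts by group (filterByExpr), which left 14876 genes holding 99.99% of the counts. Trimmed mean of M values (TMM) scaling gave factors of 0.96 to 1.03. A model with 1 mean per genotype was fitted to all 12 libraries, so that the 4 groups shared 1 estimate of the spread with 8 residual degrees of freedom and a common biological coefficient of variation of 0.209. Each difference was tested with edgeR's robust quasi-likelihood F test and Benjamini-Hochberg (BH) adjustment, and genes with an adjusted p under 0.05 were called changed. The comparisons were Blm KO, Recql KO and double KO with WT, double KO with each single KO, any difference among the genotypes, and the interaction, which is the change from Blm KO to double KO minus the change from WT to Recql KO. Levels are TMM-scaled CPM with the SD over the 3 libraries of a group, and log2 fold changes carry the standard error (SE) of the model. Where all libraries of a group held 0 counts, a fold is a lower bound against a floor of 3 counts over the group, which covers counting error only.

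Before the data were examined, 28 gene lists were fixed for pathways linked to DNA helicases, for fibroblast states and for markers of other cell types. Cdkn1a, Cdkn1c, Slc7a11, Dcn and Krt19 each stood in more than 1 list. Each was tested with limma 3.58.1, using camera with a preset correlation between genes of 0.01 and BH adjustment over the 28 lists of a comparison, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. Numbers of members that rose or fell refer to adjustment over all 14876 genes, and a second number is given adjusted over the list alone. Genes named in the text followed a rule fixed at the same time. It takes Blm, Recql, Cdkn1a, Trp53 and Cdkn2a in every comparison. It adds up to 8 genes with the highest and 8 with the lowest log2 fold change among called genes with a mean of at least 1 CPM, no predicted symbol and no overlap between the libraries of the groups. It also takes up to 4 called members of each list. The genes printed are a subset of those the rule gives, picked after their values were seen, and any gene outside it is named as such. Because the rule favours large folds and small adjusted p, the share of printed genes that keeps a call does not describe all called genes.

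Library totals ranged from 47758552 to 59296354 expected counts, so that 3 counts corresponded to 0.0506 to 0.0628 CPM. On counts simulated for Recql KO vs WT from 14738 genes, the same steps recovered 24.3% of genes changed by 1.5-fold, 69.4% of those changed by 2-fold and 92.6% of those changed by 4-fold. They called 128 genes with 200 truly changed, of which 5 calls were false. The changed genes were drawn only from genes above a minimum mean count, so recovery of genes with few counts was not measured. With no changed genes, simulated for Blm KO vs WT, edgeR called 0 genes. Gene positions came from the mm10 annotation by symbol or older symbol for 14810 of the tested genes (99.6%).

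Alternatives fixed before the data were examined were relative log expression (RLE) scaling, no filter on low counts, a filter of CPM above 1 in 3 libraries, DESeq2 1.42.0, fits on the groups compared only, the replicate number as a block, thinning every library to the smallest total, and leaving out each library in turn. After sex-linked transcripts were seen to differ between libraries, 3 more were added: the Y-linked level as a covariate, libraries with high Y-linked levels only, and libraries with low Y-linked levels only. The Y-linked level was the mean log2 CPM of Ddx3y, Eif2s3y, Kdm5d and Uty. All 12 libraries and their columns were used.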

Results

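Polyadenylated RNA was measured in primary mouse embryonic fibroblasts, connective tissue cells grown from embryos, to ask how the loss of 2 related DNA helicases changes gene expression. Blm encodes BLM, the RecQ helicase that is lost in Bloom syndrome, and Recql encodes RECQL1, another member of the same family. The 12 libraries were labelled WT, Blm KO, Recql KO and double KO, with 3 libraries per label, and each KO genotype was set against WT. The total of expected counts was 53083514, 56790963 and 52619662 in the 3 WT libraries, 57431884, 59296354 and 58816914 in Blm KO, 55387337, 57112937 and 47758552 in Recql KO and 53777808, 57353051 and 55692492 in double KO. Every pair of libraries within a label differed by far more than counting noise, with a chi-square per degree of freedom of 25.5 to 167. The labels do not say whether the libraries of a genotype came from separate embryos or cultures, so p-values measure only the spread between these libraries, part of which may be technical.

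The targeted genes were examined first. Blm (mm10 chromosome 7, 80454993 to 80535148) stood at 20.7 ± 1.85 CPM in WT (SD, n = 3), 4.13 ± 1.32 in Blm KO, 15.6 ± 1.14 in the libraries labelled Recql KO and 5.5 ± 1.57 in those labelled double KO. Relative to WT, the Blm transcript was 5.01-fold lower in Blm KO (log2 fold change -2.33 ± 0.24 SE, edgeR adjusted p = 0.00211) and 3.77-fold lower in double KO (-1.91 ± 0.24, edgeR adjusted p = 0.0105). The call in double KO was lost without WT replicate 1 (-1.87) and without double KO replicate 1 (-1.94), and also in a fit on WT and double KO alone (-1.92, edgeR adjusted p = 0.0661). With only the libraries high in Y-linked transcripts, Blm did not pass in Blm KO (-1.87, edgeR adjusted p = 0.111) or in double KO (-1.58, edgeR adjusted p = 0.154). In the libraries labelled Recql KO the Blm level did not pass the test against WT (-0.41, edgeR adjusted p = 0.197), although it did in a fit on WT and Recql KO alone (-0.41, edgeR adjusted p = 0.0242).

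Recql (chromosome 6, 142350342 to 142387100) was not lowered in the libraries labelled for its loss. Its level was 27.7 ± 1.86 CPM in WT, 22.4 ± 1.49 in Blm KO, 25.2 ± 4.16 in Recql KO and 26.3 ± 8.56 in double KO (SD, n = 3 each), or 91.2% and 95.2% of WT in the last pair. The log2 fold changes against WT were -0.13 for Recql KO and -0.07 for double KO (edgeR adjusted p = 0.642 and 0.928). A count over the whole gene does not show an allele that leaves the transcript in place, and the labels do not give the part of Recql that was targeted. The labels Recql KO and double KO are therefore used only as names of libraries, and every direction drawn from them rests on those labels.

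**Figure D1:**
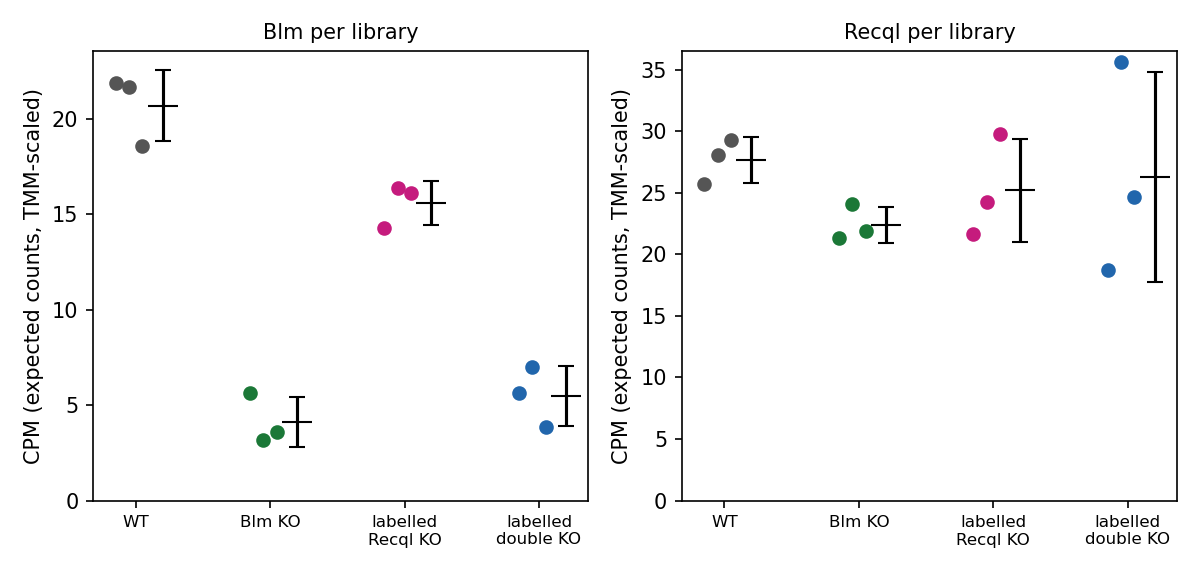
TMM-scaled CPM of Blm (left) and Recql (right) in each of the 12 libraries, with the mean and SD of the 3 libraries per label as bars. Blm stood at 4.13 CPM in Blm KO against 20.7 in WT, while Recql stood at 25.2 CPM in libraries labelled Recql KO against 27.7 in WT.

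Sex-linked transcripts differed between libraries of the same label. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 248, 229 and 257 CPM in the 3 WT libraries, 249, 1.39 and 3.45 in Blm KO, 282, 28.7 and 0.679 in Recql KO and 3.36, 247 and 6.23 in double KO. Xist, the transcript of the inactive X chromosome, was 0.536, 3.08 and 0.152 CPM in WT, 11.7, 370 and 473 in Blm KO, 0.111, 310 and 455 in Recql KO and 363, 10.3 and 453 in double KO. All WT libraries were thus high in Y-linked transcripts, as was 1 library of each other label. The library labelled Recql KO replicate 2 held both kinds of transcript, and Blm KO replicate 1 and double KO replicate 2, both high in Y-linked transcripts, held more Xist than any WT library. The first principal component took 47.3% of the variance, with the Recql KO libraries at 74.1 to 79.7 and the other 9 libraries at -54.4 to -7.02.

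**Figure D2:**
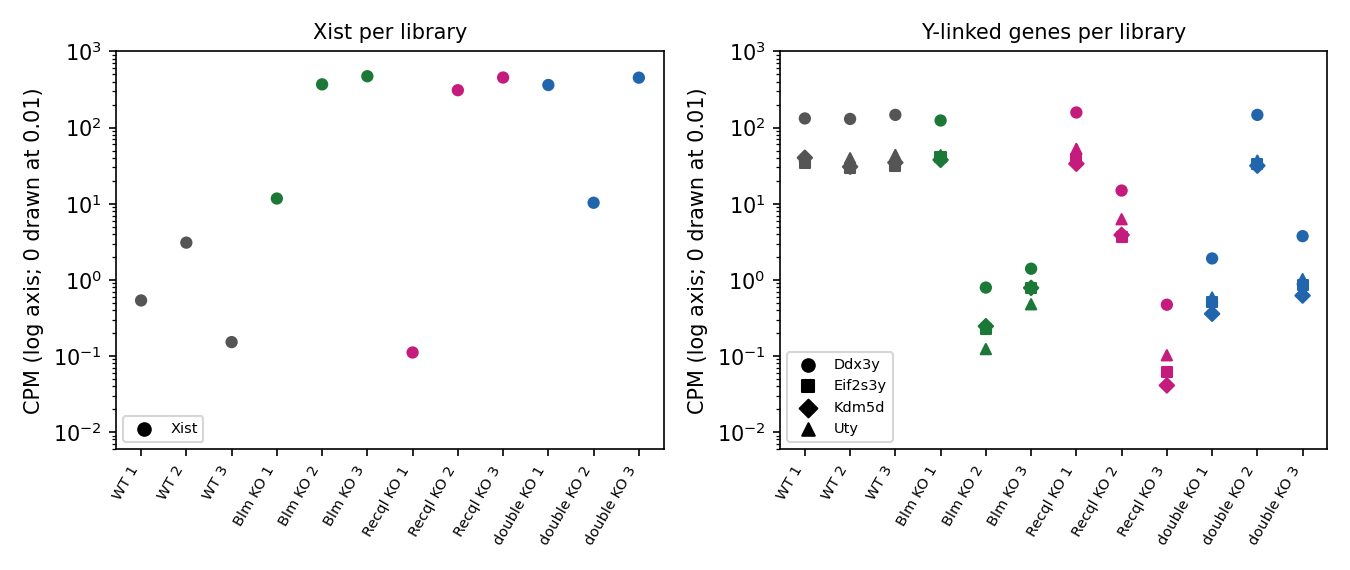
CPM of Xist (left) and of 4 Y-linked genes (right) in each of the 12 libraries, on log axes with 0 drawn at 0.01. The 3 WT libraries held 0.152 to 3.08 CPM of Xist, and Recql KO replicate 2 held 310 CPM of Xist together with 14.9 CPM of Ddx3y.

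**Figure D3:**
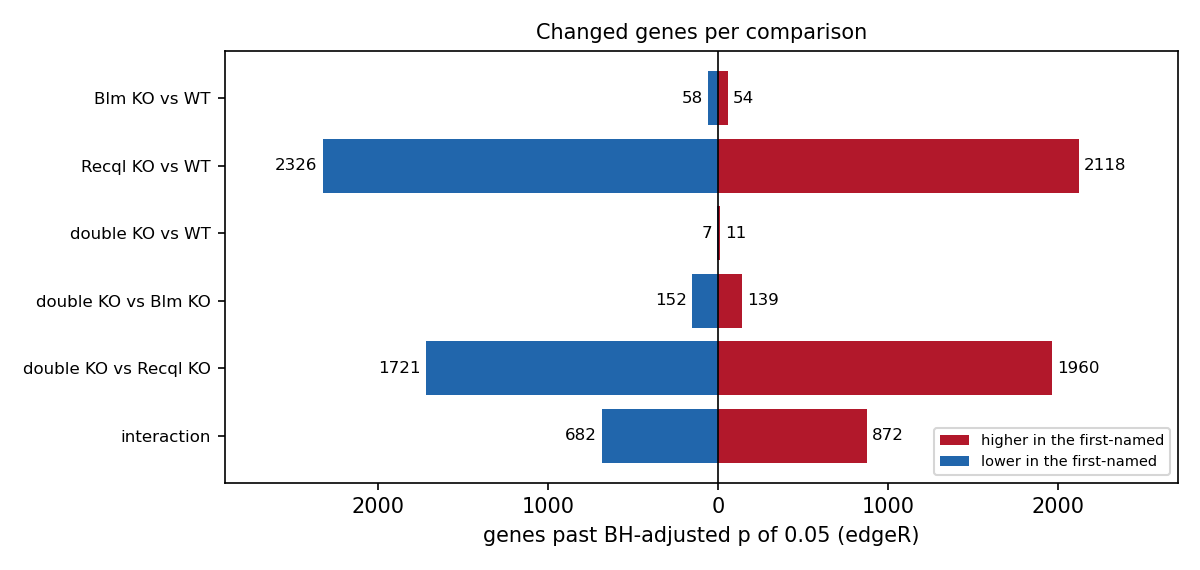
Number of the 14876 tested genes called higher (right) or lower (left) in the first-named group, per comparison, by edgeR at a BH-adjusted p of 0.05. The counts were 54 and 58 for Blm KO vs WT, 2118 and 2326 for Recql KO vs WT and 11 and 7 for double KO vs WT.

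Blm KO was compared with WT to ask which transcripts go with the Blm KO label alone. Map2, which encodes a microtubule-associated protein of neurons, rose 6.15-fold from 51.8 ± 16.4 to 319 ± 94.2 CPM (SD, n = 3; log2 fold change 2.62 ± 0.31 SE, edgeR adjusted p = 0.00432). Larger folds were seen for Ifi202b, an interferon-inducible gene of the Ifi200 cluster (367-fold higher, edgeR adjusted p = 0.00432), and for the guanylate-binding protein gene Gbp2b (288-fold higher from 6 counts in WT, edgeR adjusted p = 0.000134). Among genes that fell were Fmn2, which encodes an actin-nucleating formin (8.26-fold lower, edgeR adjusted p = 0.00432), Emx2os (7.63-fold lower), Mnda, another gene of the Ifi200 cluster (6.98-fold lower), and Rnaset2b, a lysosomal ribonuclease gene (6.14-fold lower). Atf3, a transcription factor gene induced by stress, fell from 8.07 ± 1.15 to 3.12 ± 0.152 CPM (2.59-fold lower, edgeR adjusted p = 0.00432). Ifi202b, Gbp2b, Mnda and Rnaset2b have near-identical relatives, and Emx2os is antisense to Emx2 with the strand setting of the counts not given, so that reads assigned to them are uncertain. Gbp2b and Rnaset2b were called in the opposite direction in double KO against Blm KO, although Blm was low in both groups. Their changes thus did not go with low Blm under both labels. Which changes follow from loss of BLM, rather than from other differences between the cultures, was not tested. Cdkn1a, Trp53 and Cdkn2a did not pass the test (log2 fold changes 0.26, -0.29 and 0.60, edgeR adjusted p = 0.36, 0.107 and 0.264).

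By edgeR, 112 of 14876 genes changed, 54 higher and 58 lower, with 2806 at an unadjusted p under 0.05. The count was 40 without WT replicate 1, 31 without WT replicate 2, 56 without WT replicate 3 and 34 without Blm KO replicate 3. It was 43 with the Y-linked level as a covariate, 2 with only the libraries high in Y-linked transcripts and 947 with DESeq2. Of 17 called genes followed through these fits, a subset of those the fixed rule names, 8 kept their call whichever library was left out, namely Ifi202b, Gbp2b, Map2, Fmn2, Emx2os, Mnda, Rnaset2b and Atf3.

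Proliferation lists were called downward in Blm KO by camera with the preset correlation, but not with an estimated correlation or by fry. The 32 G2/M and mitosis genes, which drive entry into and passage through cell division, had a median log2 fold change of -0.74. None passed over all genes, and 32 of 32 fell when adjusted over the list alone (camera adjusted p = 2.3e-26, adjusted p = 0.441 with an estimated correlation). For the 40 genes of DNA replication and S phase the median was -0.57, with none past the test over all genes and 32 lower when adjusted over the list alone (camera adjusted p = 5.1e-18, adjusted p = 0.464 with an estimated correlation). Homologous recombination and Fanconi anemia genes had a median of -0.45, with 0 of 31 passing over all genes and 14 lower adjusted over the list alone (camera adjusted p = 1.84e-05). For the other RecQ helicases and partners of BLM or RECQL1 the numbers were 0 of 12 and 3 lower (camera adjusted p = 0.0345, a call lost at 0.0574 without WT replicate 2 and 0.127 without Blm KO replicate 2). ER chaperone genes included Creld2, which was 1.34-fold lower (edgeR adjusted p = 0.0471, and 0.0632 to 0.211 without any 1 of the 6 libraries), as 1 of 19 over all genes and 6 lower adjusted over the list alone (camera adjusted p = 1.84e-05). The adjusted p was 0.464 with an estimated correlation for each of these last 3 lists.

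Inflammatory lists were called downward and the matrix list upward in Blm KO by camera with the preset correlation, and none of them with an estimated correlation or by fry. No gene of the interferon-stimulated list passed, and 39 of 40 had a negative log2 fold change (median -1.07, camera adjusted p = 7.83e-05, adjusted p = 0.639 with an estimated correlation). In the list of NF-kB and secretory inflammatory genes, 0 of 28 passed over all genes, while 11 were lower and 1 higher adjusted over the list alone (camera adjusted p = 7.83e-05, adjusted p = 0.464 with an estimated correlation). Cholesterol biosynthesis genes had a median of -0.63 with 0 of 24 passing (camera adjusted p = 7.88e-08, adjusted p = 0.464 with an estimated correlation). Extracellular matrix genes were the 1 list shifted upward, with a median of 0.37, 0 of 27 passing over all genes and 5 higher adjusted over the list alone (camera adjusted p = 3.55e-05, adjusted p = 0.441 with an estimated correlation). Among markers of other cell types, the endothelial list had 0 of 10 past the test over all genes and 4 lower adjusted over the list alone (camera adjusted p = 0.00134, adjusted p = 0.318 with an estimated correlation), and it was the 1 list called by fry (adjusted p = 0.0397). Macrophage and blood cell markers (camera adjusted p = 0.00169, adjusted p = 0.465 with an estimated correlation) and epithelial markers (camera adjusted p = 0.0036, adjusted p = 0.464 with an estimated correlation) were also called downward, the former not without Blm KO replicate 2 (camera adjusted p = 0.0752) and the latter not without WT replicate 3 (0.135). The neural list, which holds Map2, had a median of -0.64 with 11 of 14 below 0. Over all genes 1 member was higher (Map2) and 0 lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.0573). In all, camera called 14 of 28 lists, and 0 with an estimated correlation.

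The libraries labelled Recql KO were compared with WT to ask which transcripts go with that label alone. Prl2c2, a gene of the proliferin family of growth factors, was 337-fold higher (74.1 ± 40.4 against 0.215 ± 0.137 CPM, SD, n = 3, edgeR adjusted p = 0.000175). Saa3, which encodes an acute-phase serum amyloid protein, rose 92.4-fold (log2 fold change 6.53 ± 1.09 SE, edgeR adjusted p = 0.0021), and Serpinb2, the gene of a plasminogen activator inhibitor, rose 44.1-fold (5.46 ± 0.44, edgeR adjusted p = 0.000153). Pyhin1, an interferon-inducible gene, rose 68.7-fold (edgeR adjusted p = 0.000265). In the other direction, Col9a1, which encodes a cartilage collagen chain, fell 146-fold (edgeR adjusted p = 0.000978) and Erg, an endothelial and cartilage transcription factor gene, fell 71.3-fold from 10.4 ± 2.46 to 0.148 ± 0.122 CPM (edgeR adjusted p = 0.000219). Saa3 was 261-fold higher without WT replicate 1, and without Recql KO replicate 3 Col9a1 was 380-fold and Erg 126-fold lower. Prl2c2, Saa3 and Pyhin1 have close paralogs, so reads assigned to them are uncertain.

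By edgeR, 4444 genes (29.9%) changed, 2118 higher and 2326 lower, and 1575 of them changed by more than 2-fold, 746 higher and 829 lower. The count was 2886 without Recql KO replicate 1 and 2692 without Recql KO replicate 2. With only the libraries high in Y-linked transcripts, which leaves 1 library of that label and assumes that it varies like the other groups, 1128 genes were called. Of 46 called genes followed through these fits, a subset of those the fixed rule names, 44 kept their call whichever library was left out, and the other 2 were Brca2 and Krt8. These genes were mostly taken for large folds or small adjusted p, so their share does not describe all 4444 calls.

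Most p53 targets that changed rose, CDK inhibitor genes went both ways and mitotic genes fell. Cdkn1a, which encodes the CDK inhibitor p21, rose 1.91-fold (log2 fold change 0.94 ± 0.15 SE, edgeR adjusted p = 0.00174) and Cdkn2a, the locus of p16 and ARF, rose 2.39-fold (1.26 ± 0.27, edgeR adjusted p = 0.00763), while Trp53 did not pass (0.16, edgeR adjusted p = 0.13). Of 29 p53 targets, 14 rose and 1 fell, and 17 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.44e-05, adjusted p = 0.406 with an estimated correlation). Mdm2, the p53 ubiquitin ligase gene, rose from 310 ± 32.2 to 710 ± 48 CPM, and Plk2, a polo-like kinase gene, rose 2.15-fold. Among 8 CDK inhibitor genes 3 rose and 4 fell, or 3 and 5 adjusted over the list alone (median -0.86, camera adjusted p = 0.0122, adjusted p = 0.201 with an estimated correlation). Cdkn1b, which encodes p27 and lies 7.45 Mb from Recql, fell from 63.7 ± 8 to 20.6 ± 2.82 CPM (3.09-fold, edgeR adjusted p = 9.15e-05), and Cdkn3 fell 3.71-fold. In the G2/M and mitosis list 25 of 32 fell and 0 rose, with 32 lower adjusted over the list alone (median -0.80, camera adjusted p = 4.52e-12, adjusted p = 0.406 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell 2.24-fold and the cyclin gene Ccnb2 fell 2.2-fold (edgeR adjusted p = 0.00173 and 0.00248).

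Lists of DNA replication and repair were not called in the libraries labelled Recql KO. Of 40 DNA replication and S phase genes 4 rose, among them E2f1 (1.4-fold), and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.683). Of 22 chromatid cohesion genes 1 rose and 2 fell, among them the cohesin gene Rad21 (1.44-fold), again with the same numbers adjusted over the list alone (camera adjusted p = 0.254). Of 31 homologous recombination and Fanconi anemia genes 2 rose and 3 fell over all genes and adjusted over the list alone (camera adjusted p = 0.439). Brca2 was 1.5-fold higher (edgeR adjusted p = 0.0237), a call lost without WT replicate 2 or 3 (adjusted p = 0.066 and 0.0726) and without Recql KO replicate 2 or 3 (0.064 and 0.0714). Of 12 other RecQ helicases and partners 0 rose and 3 fell by either adjustment, among them Wrn, the Werner syndrome helicase gene (1.38-fold), and Parp1 (1.45-fold). That list had a median just above 0, a mean of -0.06 and a downward test (camera adjusted p = 0.57). Of 18 replication checkpoint genes 1 rose, the DNA damage kinase gene Atm (1.43-fold, edgeR adjusted p = 0.00111), and 1 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.607).

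Stress and inflammatory lists shifted upward with the Recql KO label. NRF2 targets, genes of the antioxidant response, had 13 of 20 members higher and 1 lower, or 15 and 1 adjusted over the list alone, with a median of 0.67. The shift was called by camera (adjusted p = 9.39e-10) and was the 1 list still called with an estimated correlation (adjusted p = 0.0363). Nqo1, a quinone reductase gene, rose from 20.6 ± 3.78 to 86.3 ± 11.6 CPM (4.19-fold, edgeR adjusted p = 0.000527). Hmox1, the heme oxygenase gene, rose 3.74-fold, Gclc, which encodes the catalytic subunit for glutathione synthesis, rose 2.26-fold and Srxn1, the sulfiredoxin gene, rose 2.16-fold. In the interferon-stimulated list 25 of 40 rose and 0 fell, with 33 higher adjusted over the list alone (camera adjusted p = 1.13e-10, adjusted p = 0.406 with an estimated correlation). Examples were Rsad2, which encodes viperin (31.7-fold, and 53.4-fold without WT replicate 1), and Oas3, an oligoadenylate synthetase gene (7.92-fold). NF-kB and secretory inflammatory genes had 12 of 28 higher and 0 lower, or 13 and 0 adjusted over the list alone, including Ptgs2, the cyclooxygenase-2 gene (2.23-fold), and Vegfa (2.02-fold; camera adjusted p = 7.26e-06, adjusted p = 0.306 with an estimated correlation). Glycolysis and hypoxia genes had 7 of 22 higher and 0 lower, or 10 and 0 adjusted over the list alone, with the hexokinase gene Hk2 at 2.57-fold (camera adjusted p = 5.51e-05, adjusted p = 0.483 with an estimated correlation).

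Secretory and lipid pathways moved the other way. ER chaperone genes had 1 of 19 higher and 10 lower, or 1 and 13 adjusted over the list alone, among them Hspa5, which encodes BiP (1.66-fold lower; camera adjusted p = 9.05e-05, adjusted p = 0.406 with an estimated correlation). Cholesterol biosynthesis genes had 0 of 24 higher and 10 lower, or 0 and 16 adjusted over the list alone, among them the mevalonate kinase gene Mvk (2.11-fold) and Dhcr7 (2.2-fold; camera adjusted p = 2.9e-05, adjusted p = 0.54 with an estimated correlation). ATF4 and integrated stress response genes went both ways, with 3 of 24 higher and 7 lower by either adjustment (camera adjusted p = 0.433). Within them, Ddit3, which encodes CHOP, rose 2.45-fold and the serine synthesis gene Psat1 fell 1.9-fold.

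Matrix, imprinted and patterning genes also changed with the Recql KO label. Eln, which encodes elastin, fell from 61.9 ± 11.1 to 1.85 ± 1.24 CPM (33.8-fold, edgeR adjusted p = 0.00016, and 53.7-fold without Recql KO replicate 3) and Col3a1 fell 4.39-fold. In that list 4 of 27 rose and 12 fell, or 4 and 13 adjusted over the list alone (camera adjusted p = 0.00456, adjusted p = 0.362 with an estimated correlation). Imprinted growth genes, expressed from 1 parental copy, had 1 of 19 higher and 13 lower, or 1 and 14 adjusted over the list alone (camera adjusted p = 4.58e-09, adjusted p = 0.306 with an estimated correlation). Mest fell 99.3-fold (306 ± 301 against 3.09 ± 0.835 CPM), the noncoding RNA H19 fell 56.1-fold and the growth factor gene Igf2 fell 44.1-fold (edgeR adjusted p = 0.000487, 0.00151 and 0.00423). Without WT replicate 3 these folds were 43.1, 27.4 and 25.5. Hox genes, which encode positional transcription factors, had 15 of 36 higher and 7 lower, or 17 and 8 adjusted over the list alone, with Hoxb4 at 2.66-fold and Hoxb8 at 2.34-fold higher (camera adjusted p = 0.0122, adjusted p = 0.306 with an estimated correlation).

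Markers of other cell types moved with these groups in the libraries labelled Recql KO. Cartilage markers had 0 of 15 higher and 11 lower, or 0 and 12 adjusted over the list alone (camera adjusted p = 2.35e-10, adjusted p = 0.19 with an estimated correlation), and Col2a1 fell from 756 ± 449 to 40 ± 17.3 CPM (18.9-fold, and 12.4-fold without WT replicate 3). Mesothelial markers had 0 of 14 higher and 4 lower, or 0 and 6 adjusted over the list alone, with Msln 18.8-fold lower, or 9.97-fold without WT replicate 3 (camera adjusted p = 0.0112, adjusted p = 0.406 with an estimated correlation). Epithelial markers had 0 of 12 higher and 5 lower by either adjustment (camera adjusted p = 0.0238, adjusted p = 0.483 with an estimated correlation). Krt8, 1 of the 5, was 23.8-fold lower (edgeR adjusted p = 0.0135, and 0.056 without Recql KO replicate 1), or 12.7-fold without WT replicate 3. Adipocyte markers had 0 of 6 higher and 3 lower, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.306 with an estimated correlation). Skeletal muscle markers had 2 of 15 higher and 6 lower, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.227), and Myh8, a perinatal myosin gene with 0 counts in these libraries, was at least 15.6-fold lower against a floor of 3 counts over the group. Camera did not call the endothelial (0 of 10 higher, 4 lower, camera adjusted p = 0.0859) or macrophage and blood cell lists (1 of 13 higher, 2 lower, 0.116). Nor did it call the neural list (2 of 14 higher, 0 lower, 0.393). The myofibroblast and smooth muscle (0 of 14 higher, 2 lower, 0.525) and sex-linked lists (1 of 5 higher, 0 lower, 0.628) were not called by camera either. In each of these lists the numbers were the same adjusted over the list alone. In the myofibroblast list the median was 0.06 against a mean of -0.11 and a downward test, and in the sex-linked list the median was -1.17 and the test downward against a mean of 0.53. Camera called 16 of 28 lists in all, 6 upward and 10 downward, and 1 with an estimated correlation. Fry called 17 lists, among them the endothelial (fry adjusted p = 0.00693) and skeletal muscle lists (0.0478), both downward and not called by camera.

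**Figure D4:**
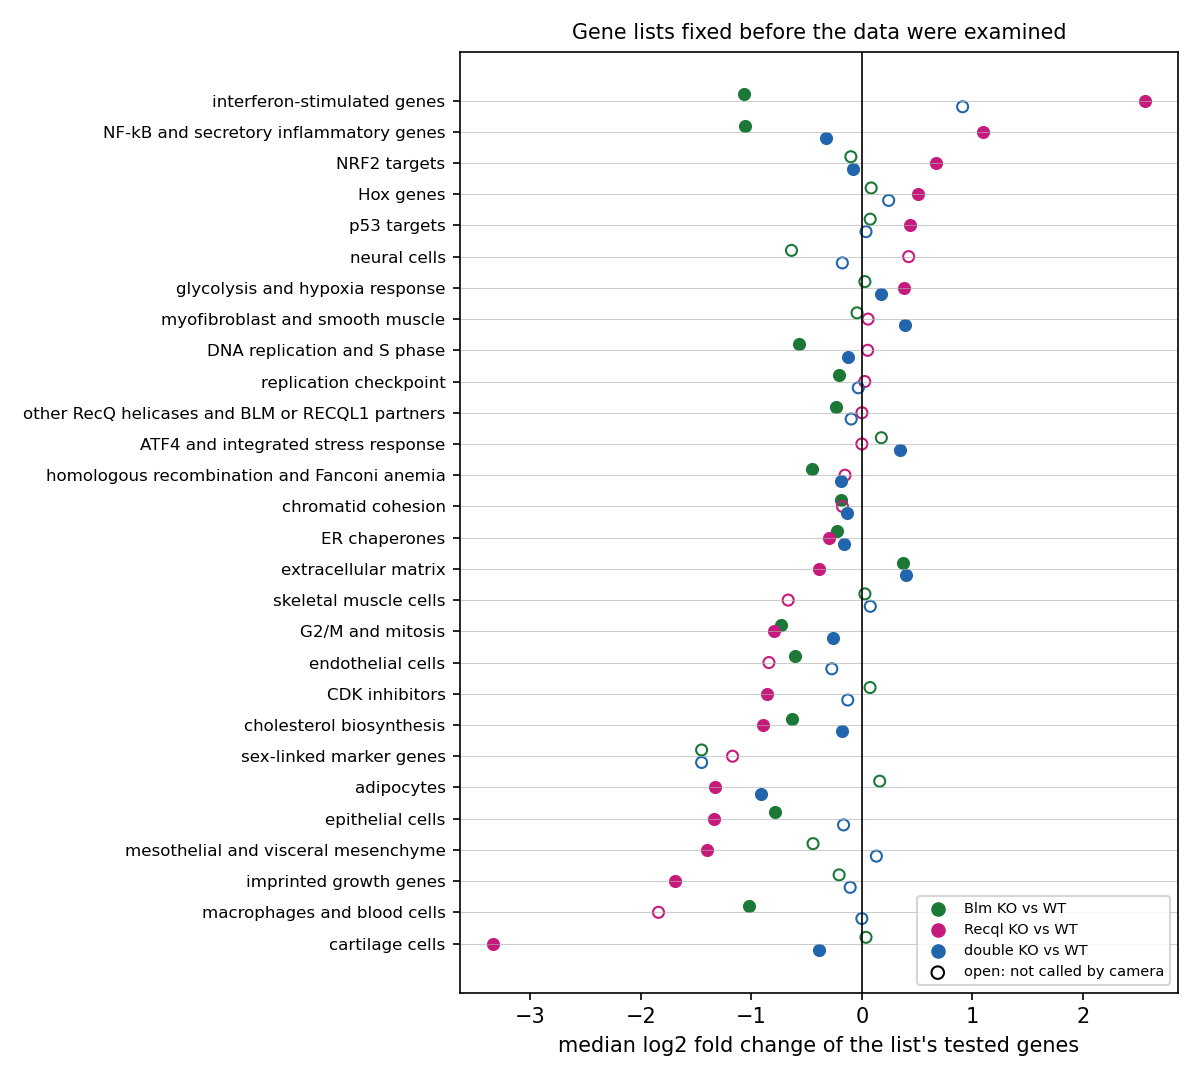
Median log2 fold change of the tested genes of each of the 28 gene lists in Blm KO, Recql KO and double KO against WT, with filled points for lists called by camera at a BH-adjusted p of 0.05. With the Recql KO label, interferon-stimulated genes had a median of 2.56 and cartilage markers one of -3.34.

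The libraries labelled double KO were compared with WT to ask which transcripts go with loss of both genes. Beyond Blm, few genes passed. Cd200, which encodes an immunoregulatory surface glycoprotein, was 7.11-fold higher (log2 fold change 2.83 ± 0.30 SE, n = 3 per group, edgeR adjusted p = 0.00561), and Pdgfrl, a gene related to platelet-derived growth factor receptors, was 3.31-fold higher (edgeR adjusted p = 0.00585). Hddc3, which lies 0.15 Mb from Blm, was 4.98-fold higher (edgeR adjusted p = 0.0041). Emx2os was 3.29-fold lower (edgeR adjusted p = 0.00839). Ifi202b was 619-fold higher (9.27 ± 1.03, edgeR adjusted p = 0.00635), Atp10d, a phospholipid flippase gene, was 8.89-fold higher and the galectin gene Lgals3 was 1.76-fold lower, but all 3 calls were lost without WT replicate 1 (edgeR adjusted p = 0.0501, 0.0556 and 0.0501) and without WT replicate 3 (0.0631, 0.0771 and 0.095). Without double KO replicate 1 Ifi202b was 264-fold higher. The call of Lgals3 was also lost without double KO replicate 2 or 3 (0.0593 and 0.0813). Cdkn1a, Trp53 and Cdkn2a did not pass (log2 fold changes 0.45, -0.10 and 0.31, edgeR adjusted p = 0.328, 0.693 and 0.737).

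By edgeR, 18 genes changed, 11 higher and 7 lower, with 1605 at an unadjusted p under 0.05. The count was 28 without WT replicate 2, 8 without WT replicate 3, 45 with the Y-linked level as a covariate, 3 with only the libraries high in Y-linked transcripts and 337 with DESeq2. In an edgeR fit on these 6 libraries alone it was 0, with 1243 genes at an unadjusted p under 0.05.

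Matrix and ATF4 lists were shifted upward in double KO by camera with the preset correlation, along with cell type lists in both directions. Extracellular matrix genes had a median log2 fold change of 0.40, with 25 of 27 above 0, 0 past the test over all genes and 9 higher adjusted over the list alone (camera adjusted p = 6.41e-11, adjusted p = 0.0866 with an estimated correlation, fry adjusted p = 0.0375). ATF4 and integrated stress response genes had a median of 0.35, with 0 of 24 past the test over all genes and 9 higher adjusted over the list alone (camera adjusted p = 1.93e-07, adjusted p = 0.212 with an estimated correlation). Adipocyte markers had a median of -0.91, with 0 of 6 past the test over all genes and 1 lower adjusted over the list alone (camera adjusted p = 2e-04, adjusted p = 0.0866 with an estimated correlation, fry adjusted p = 0.0453). Myofibroblast and smooth muscle genes had a median of 0.39 (camera adjusted p = 3.34e-05) and cartilage markers one of -0.39 (camera adjusted p = 0.0346), with 0 of 14 and 0 of 15 past the test by either adjustment and an adjusted p of 0.678 with an estimated correlation for both. The cartilage call was lost without WT replicate 3 (0.528) and without double KO replicate 2 or 3 (0.0999 and 0.127). G2/M and mitosis genes had a median of -0.26 and no member past the test by either adjustment (camera adjusted p = 1.36e-06, adjusted p = 0.678 with an estimated correlation, and 0.244 without double KO replicate 3). Camera called 14 of 28 lists and 0 with an estimated correlation, and 7 without double KO replicate 3.

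Double KO was set against Blm KO to ask what goes with the added Recql KO label when Blm is lost. Rnaset2b rose from 2.05 ± 0.422 to 15.3 ± 2.85 CPM (SD, n = 3; 7.43-fold, edgeR adjusted p = 0.000199), and Scel, which encodes sciellin of the cornified envelope, rose 5.91-fold (log2 fold change 2.56 ± 0.28 SE, edgeR adjusted p = 0.00399). Gbp2b, with 0 counts in double KO, was at least 609-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 6.73e-05). Map2 fell 3.06-fold (edgeR adjusted p = 0.0306), Comp, a cartilage matrix gene, fell 11.7-fold and Penk, the proenkephalin gene, fell 10.1-fold, while Atf3 rose 2.12-fold (edgeR adjusted p = 0.0168) and the matrix genes Tnc and Loxl2 rose 2.47-fold and 2.36-fold. The matrix list was not called, with 3 of 27 higher and 0 lower by either adjustment and 17 below 0 (median -0.04, camera adjusted p = 0.37). Of 29 p53 targets 2 rose and 0 fell by either adjustment, Plk2 (1.4-fold) and Pmaip1, which encodes NOXA (1.73-fold), with 17 below 0 and no call of the list (camera adjusted p = 0.434). Cdkn1b fell 1.41-fold (edgeR adjusted p = 0.0482). Endothelial markers Flt1 and Emcn rose 5.64-fold and 4.07-fold, and Flt1 stood 3.35-fold higher without double KO replicate 2 (edgeR adjusted p = 0.101). The calls of Map2, Comp, Penk, Atf3, Tnc, Loxl2, Plk2, Pmaip1, Cdkn1b, Flt1 and Emcn were all lost without Blm KO replicate 3 (adjusted p from 0.108 to 0.188) and without double KO replicate 2 (0.0595 to 0.147). Those of Tnc, Pmaip1, Cdkn1b, Flt1 and Emcn were also lost without Blm KO replicate 1 or double KO replicate 1, as were that of Plk2 without the former and that of Map2 without the latter (0.0532 to 0.118). Flt1 also lost its call without Blm KO replicate 2 (0.0624) and Cdkn1b without double KO replicate 3 (0.0548). Rnaset2b, Scel and Gbp2b kept their call whichever library was left out, as 3 of 24 called genes followed through these fits. In Blm KO vs WT, Rnaset2b, Gbp2b, Map2 and Atf3 had been called in the opposite direction (log2 fold changes -2.618, 8.168, 2.62 and -1.372). The same Blm KO libraries stand in both comparisons, so these changes may belong to those libraries rather than to the added label.

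By edgeR, 291 genes changed, 139 higher and 152 lower. The count was 585 without Blm KO replicate 2, 9 without Blm KO replicate 3, 89 without double KO replicate 1, 15 without double KO replicate 2 and 520 without double KO replicate 3. It was 8 in a fit on these 6 libraries alone, 31 with only the libraries low in Y-linked transcripts and 1404 with DESeq2.

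Proliferation and interferon-stimulated lists, called downward in Blm KO against WT, were called upward in double KO against Blm KO by camera with the preset correlation, with the same Blm KO libraries in both. G2/M and mitosis genes had a median of 0.48 (camera adjusted p = 3.39e-08), DNA replication and S phase genes one of 0.40 (camera adjusted p = 2.51e-07) and interferon-stimulated genes one of 2.04 (camera adjusted p = 3.16e-05), with 0 of 32, 0 of 40 and 0 of 40 members past the test over all genes or adjusted over the list alone. The adjusted p was 0.708 with an estimated correlation for each of the 3, and without double KO replicate 1 the interferon-stimulated list turned downward (camera adjusted p = 0.69). Endothelial markers had 2 of 10 higher, or 3 adjusted over the list alone, with 0 lower (camera adjusted p = 0.0257, adjusted p = 0.708 with an estimated correlation), a call lost without Blm KO replicate 3 (0.0548) and double KO replicate 1 (0.0554). Other cell type lists were called as well, upward for myofibroblast and smooth muscle genes (0 of 14 past either adjustment, camera adjusted p = 0.000273), neural markers (0 of 14 higher and 1 lower, or 7 and 2 adjusted over the list alone, camera adjusted p = 0.0181), macrophage and blood cell markers (0 of 13 past either adjustment, 0.0247) and epithelial markers (0 of 12 past either adjustment, 0.0423). Adipocyte markers were called downward (0 of 6 higher and 1 lower, or 1 and 4 adjusted over the list alone, camera adjusted p = 0.0285). For each of these 5 the adjusted p was 0.708 with an estimated correlation. Without Blm KO replicate 2 the neural, macrophage, epithelial and adipocyte calls were lost (0.143, 0.218, 0.207 and 0.0759), as were the first 3 without double KO replicate 1 (0.054, 0.222 and 0.134) and the last without double KO replicate 3 (0.124). Camera called 12 of 28 lists, 11 upward and 1 downward, and 7 without Blm KO replicate 2. It called 0 with an estimated correlation, and fry called 0.

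Double KO was also set against the libraries labelled Recql KO, the comparison in which Blm differs between groups that share the Recql label. Blm was 2.83-fold lower in double KO (log2 fold change -1.50 ± 0.24 SE, n = 3 per group, edgeR adjusted p = 0.00185). Eln was 80.5-fold, Col9a1 125-fold, Mest 45.1-fold and Igf2 42.8-fold higher in double KO (edgeR adjusted p = 0.000107, 0.00124, 0.000974 and 0.00503). Prl2c2 was 427-fold, Pyhin1 217-fold and Serpinb2 43.1-fold lower, and so were Nos2, the inducible nitric oxide synthase gene (328-fold), and Lcn2, the lipocalin-2 gene (57.2-fold), with edgeR adjusted p from 0.000107 to 0.00278. Without Recql KO replicate 3 Col9a1 was 326-fold and Eln 128-fold higher. Without double KO replicate 1 Igf2 was 25.1-fold higher, and Prl2c2 was 1580-fold, Pyhin1 747-fold and Lcn2 152-fold lower. Pyhin1 was 144-fold lower without double KO replicate 2, and Nos2 498-fold lower without double KO replicate 3. Cdkn1a, Cdkn2a and Trp53 were 1.4-fold, 1.93-fold and 1.2-fold lower (edgeR adjusted p = 0.0374, 0.0285 and 0.0298), but these calls depended on single libraries. Those of Cdkn1a and Cdkn2a were lost without any 1 of the 6 libraries other than double KO replicate 3 (adjusted p up to 0.116 and 0.0737), and that of Trp53 was lost without any other than Recql KO replicate 1 and double KO replicate 2 (up to 0.103). By edgeR, 3681 genes changed, 1960 higher and 1721 lower. The count was 2250 without Recql KO replicate 1 and 2157 without Recql KO replicate 2.

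Several gene groups lay opposite to their shift in Recql KO vs WT, with the same Recql KO libraries in both. NRF2 targets had 0 of 20 higher and 14 lower in double KO, or 0 and 15 adjusted over the list alone, with a median of -0.84 (camera adjusted p = 2.24e-15, and adjusted p = 0.00698 with an estimated correlation). Nqo1 was 6.74-fold, Gclc 2.42-fold and Srxn1 2.17-fold lower. Inflammatory NF-kB genes had 2 of 28 higher and 16 lower, or 2 and 18 adjusted over the list alone, with Ptgs2 2.87-fold lower (camera adjusted p = 8.77e-09, adjusted p = 0.223 with an estimated correlation). Interferon-stimulated genes had 0 of 40 higher and 9 lower by either adjustment, with Cxcl10 27.3-fold lower (camera adjusted p = 1.66e-09, adjusted p = 0.48 with an estimated correlation). Extracellular matrix genes had 14 of 27 higher and 0 lower by either adjustment, with Col3a1 6.37-fold higher (camera adjusted p = 4.69e-10, adjusted p = 0.0679 with an estimated correlation). G2/M and mitosis genes had 11 of 32 higher and 0 lower, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.65e-06, adjusted p = 0.548 with an estimated correlation). Cartilage markers had 11 of 15 higher and 0 lower by either adjustment, with Col2a1 15.3-fold higher (camera adjusted p = 8.49e-09, adjusted p = 0.153 with an estimated correlation). Imprinted growth genes had 12 of 19 higher and 0 lower, or 14 and 1 adjusted over the list alone (camera adjusted p = 1.37e-07, adjusted p = 0.341 with an estimated correlation). The ATF4 list, not called in Recql KO vs WT, had 12 of 24 higher and 4 lower, or 13 and 4 adjusted over the list alone, with the amino acid genes Cth and Slc7a5 3.71-fold and 2.61-fold higher (camera adjusted p = 0.000377, adjusted p = 0.399 with an estimated correlation). Camera called 17 of 28 lists, and 1 with an estimated correlation, while fry called 14.

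The interaction asked whether the change that goes with the Recql KO label differed between cells with and without Blm. Eln was 33.8-fold lower in Recql KO than in WT and stood at 147 ± 45.8 CPM in double KO against 123 ± 38.4 in Blm KO (SD, n = 3), an interaction of 5.34 ± 0.59 (log2, SE, edgeR adjusted p = 0.00266). Without Recql KO replicate 3 the fold was 53.7 and the interaction 6.003. Serpinb2 and Hmox1 rose with the label in cells with Blm and had interactions of -5.70 ± 0.61 and -2.42 ± 0.33 (edgeR adjusted p = 0.00231 and 0.0043), as had Mdm2 (-0.92 ± 0.18, edgeR adjusted p = 0.0133). Cdc20, a mitotic gene, had one of 1.52 ± 0.26 and Cdkn1b one of 1.13 ± 0.16 (edgeR adjusted p = 0.00876 and 0.00454). For Cdkn1a and Cdkn2a the interactions were -0.75 and -1.55 (edgeR adjusted p = 0.0472 and 0.0317), calls lost without most single libraries (adjusted p up to 0.113 and 0.0741). The call of Cdkn1a was kept without Blm KO replicate 1 or double KO replicate 3, and that of Cdkn2a without either of these or double KO replicate 1. For Trp53 it was 0.03 (edgeR adjusted p = 0.885).

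By edgeR, 1554 genes had an interaction, 872 positive and 682 negative. The count was 880 without WT replicate 2, 1016 without WT replicate 3, 549 without Blm KO replicate 3, 797 without Recql KO replicate 1, 648 without Recql KO replicate 2 and 938 without Recql KO replicate 3. It was 829 with the Y-linked level as a covariate and 2616 with DESeq2. Any difference among the 4 genotypes was called for 5342 genes (35.9%), for 3298 without Recql KO replicate 1 and for 3012 without Recql KO replicate 2.

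Of the gene groups, G2/M and mitosis had a positive interaction in 27 of 32 genes and a negative one in 0, or 32 and 0 adjusted over the list alone, with a median of 1.28 (camera adjusted p = 1.69e-25, adjusted p = 0.251 with an estimated correlation). NRF2 targets had a negative one in 9 of 20 and a positive one in 0, or 11 and 0 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 1.54e-10, and adjusted p = 0.0313 with an estimated correlation). Cholesterol biosynthesis had 7 of 24 positive, or 17 adjusted over the list alone, with 0 negative (camera adjusted p = 6.66e-09, adjusted p = 0.397 with an estimated correlation). ER chaperones, with Hspa5 at 0.87, had 8 of 19 positive and 1 negative, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.52e-06, adjusted p = 0.327 with an estimated correlation). Cartilage markers moved with these groups, with 8 of 15 positive, or 12 adjusted over the list alone, and 0 negative (camera adjusted p = 1.81e-08, adjusted p = 0.193 with an estimated correlation).

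**Figure D5:**
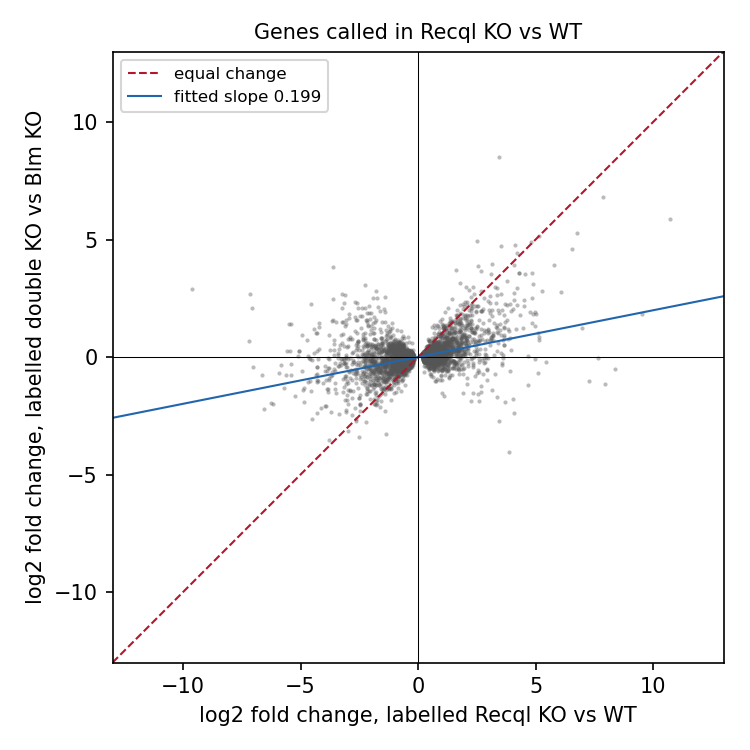
Log2 fold change of double KO vs Blm KO against that of Recql KO vs WT for the 4444 genes called in the latter, 1 point per gene. The fitted slope (solid line) was 0.199, against 1 for equal change (dashed line).

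Overlaps of the calls against WT share the same 3 WT libraries, which cannot be divided into parts of at least 2 libraries, so that part of any excess may come from the shared controls. Blm KO and double KO had 13 genes called in the same direction, 9 higher and 4 lower, with 0 in opposite directions by edgeR. Among these 13 were Blm, Ifi202b, Atp10d, Cd200, Hddc3, Pdgfrl, Uggt2, the pseudogenes Rps15a-ps4 and Rps15a-ps6, and Emx2os. Unchanged groups simulated around the means of these same WT libraries gave a median and maximum of 0, and independent lists would give 0.0399 higher and 0.0273 lower. Such groups leave out the deviation of the WT libraries, so simulated overlaps, correlations and covariances lie near 0 by construction. They cannot show how much of an excess comes from the shared controls. The number was 7 without WT replicate 1, 6 without WT replicate 3 and 0 with fits on the groups compared alone, and 98 with DESeq2. Across genes, the correlation of the log2 fold changes was 0.267 against a simulated median of 0.0202, and the covariance 0.0794 against 0.00121. For Recql KO and double KO, 2 genes were called in the same direction and 4 in opposite directions, against 1.57 higher and 1.09 lower for independent lists, and the covariance was 0.135 against a simulated 0.00114. The 2 became 10 without WT replicate 2, 0 without WT replicate 3, 4 and 5 without Recql KO replicates 1 and 3, 1 without double KO replicate 1 or 3, and 158 with DESeq2. The genes in the same direction were Rab3b and Txnip, the latter outside the fixed rule and chosen after its values were seen. For Blm KO and Recql KO, 16 genes were called in the same direction and 22 in opposite directions, against 7.69 higher and 9.07 lower for independent lists, and the covariance was -0.0102 against a simulated 0.000801. The 16 became 3, 2 and 6 without WT replicates 1, 2 and 3, 2 without Blm KO replicate 3, 5, 3 and 6 without Recql KO replicates 1, 2 and 3, and 221 with DESeq2.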

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

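The tests of equal action and of fewer other cells were chosen after their results were seen, and the covariate for Y-linked transcripts was chosen after those transcripts were seen. The interaction test found that 1554 genes and 22 gene lists changed differently with the Recql KO label when Blm was lost. With an estimated correlation, 1 of these lists was called. In 100 ways of dividing the 12 libraries, the real one included, 2 gave at least 1554 interaction genes, 1 gave at least 5342 genes differing among the groups and 1 gave at least 22 interaction lists. The highest other values were 4446, 4302 and 20, and each share was under 0.05. Interaction lists numbered 5 to 20 in the divisions other than the real one, so camera with the preset correlation called lists in mixed groups too. For the genes, the share reflects how rarely the 3 libraries labelled Recql KO fell together. This happened in 3 of the 100 divisions, with 1554, 1136 and 4446 interaction genes. The other divisions gave at most 158 interaction genes and at most 8 genes differing among the groups. Of the 3 divisions that kept these libraries together 2 reached 1554, so that chance is not excluded for the interaction beyond the structure of the samples, in which the libraries labelled Recql KO stand apart from the other 9.

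The named genes that the interaction test called are given as log2 interactions, which are positive where the change from Blm KO to double KO lay above the change from WT to Recql KO. Those at 2 or more were Ibsp at 10.06, Col9a1 7.89, Heyl 7.46, Krt8 6.84, Myh8 6.60, Ndufs5 6.20, Mest 5.88, Igf2 5.70, Msln 5.69, H19 5.49, Eln 5.34, Akap5 4.61, Erg 4.17, Col2a1 4.14, Scel 3.97, Emcn 3.49, Flt1 2.85, Cd200 2.49, Rnaset2b 2.44, Cdkn3 2.08 and Col3a1 2.06. Smaller positive ones were Cth at 1.71, Cdc25c 1.64, Ccnb2 1.58, Cdc20 1.52, Dhcr7 1.5, Pdgfrl 1.48, Kif20a 1.44, Mvk 1.195, Psat1 1.14, Cdkn1b 1.13, Emx2os 1.08, Atf3 0.89, Hspa5 0.87, Slc7a5 0.87, Creld2 0.62, Rad21 0.61 and Parp1 0.61. Negative ones were Atm at -0.42, E2f1 -0.62, Plk2 -0.62, Cdkn1a -0.75, Lgals3 -0.78, Vegfa -0.80, Mdm2 -0.92, Srxn1 -0.99, Hoxb8 -1.07, Gclc -1.09, Ptgs2 -1.32, Ddit3 -1.45, Cdkn2a -1.55, Nqo1 -2.18, Hmox1 -2.42, Sytl1 -2.48, Penk -3.53, Gfra2 -4.49, Tnfrsf9 -5.07, Serpinb2 -5.70, Prl2c2 -8.92, Prl2c3 -9.06 and Gbp2b -10.08. The values of Gbp2b and Myh8 rest on a group with 0 counts and depend on the prior count of the fit. Other values moved when 1 library was left out. Without WT replicate 3 Mest stood at 4.67, H19 at 4.45 and Msln at 4.76. Prl2c3 stood at -6.315 without Blm KO replicate 2. In the other direction, Col9a1 reached 9.26 and Prl2c2 reached -10.81 with 1 library left out.

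Of these 61 genes 40 kept the interaction call whichever of the 12 libraries was left out, and 21 lost it in at least 1 such fit. Named genes were mostly taken for large folds or small adjusted p, so this share does not describe all interaction calls. Ibsp kept it in 3 of the 12 fits and fell to 5.57 without double KO replicate 2, which held 58.03 CPM against 1.45 and 0.329 in the other double KO libraries. The call was kept in 2 fits for Emx2os, Cdkn1a and Vegfa, in 3 for Cdkn2a and Sytl1, in 4 for Atf3, Slc7a5, Rad21 and Atm, in 5 for Flt1, in 6 for Dhcr7, Mvk and Parp1, in 7 for Ndufs5 and Igf2, in 8 for Gfra2 and in 9 for Krt8. It was lost without Blm KO replicate 3 for H19 (adjusted p = 0.0501), without Blm KO replicate 2 for Prl2c3 (0.177) and without Recql KO replicate 1 for Gbp2b (1), by edgeR. By library left out, the number of calls lost was 11, 16 and 9 for WT replicates 1, 2 and 3, 3, 13 and 19 for Blm KO, 16, 18 and 14 for Recql KO and 6, 5 and 4 for double KO.

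Libraries labelled Recql KO differed from WT by 4444 genes, while libraries labelled double KO differed from Blm KO by 291. A loss of Recql acting alike with and without Blm was argued against by a slope of 0.199 over the 4444 genes (0.144 to 0.264 with 1 library left out), where 1 would be equal action, although choosing these genes by their call lowers the slope by itself and 66.5% had the same sign in both. As the whole cause, library depth was argued against by 4405 calls after thinning to 1 total, and the sex of the cells by 3529 calls with the Y-linked level as a covariate. All WT libraries were high in Y-linked transcripts, so the covariate drew mainly on the other labels, and its use for WT was assumed. Fewer genes were called with only the libraries high in Y-linked transcripts, which leaves 1 library labelled Recql KO. Blm KO and double KO had the same make-up as Recql KO, 1 library high and 2 low, with 112 and 18 calls against WT. Fewer cells of other types, as the whole cause, was argued against by 746 genes called higher by over 2-fold. That test assumes that the lost cells were a minority, whose loss raises other transcripts by less than 2-fold. The share of such cells was not measured. An effect of Recql loss that depends on Blm, a difference in age or state of the cultures labelled Recql KO, and a wrong label of that group may each account for the rest and were not tested. The Recql transcript at 91.2% of WT in these libraries does not separate them.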

How the results depend on the processing

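The alternatives that use Y-linked transcripts were chosen after the data were seen. Over all alternatives, 2134 values of named genes kept direction and side of the threshold, 337 lost the call, 1 gained it and 10 reversed. Counts of changed genes stayed within 1.5 times in 75 fits and left that range in 38. RLE scaling, a filter of CPM above 1 in 3 libraries and thinning to the smallest total moved no count of changed genes by more than 1.5 times. DESeq2 shared all 112 calls of Blm KO vs WT, all 18 of double KO vs WT and all 291 of double KO vs Blm KO while calling more. Thinning left 4405 calls of Recql KO vs WT and 100 of Blm KO vs WT, so that the range of depth between these libraries limited few calls. The cause of the changes listed here was not tested, except that fits on fewer libraries have fewer degrees of freedom.

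Leaving out 1 library at a time, changed genes ranged from 31 to 114 (Blm KO vs WT), 2692 to 3715 (Recql KO vs WT), 8 to 28 (double KO vs WT), 9 to 585 (double KO vs Blm KO), 2157 to 3519 (double KO vs Recql KO), 549 to 1836 (interaction) and 3012 to 5872 (any genotype). Lists ranged from 7 to 17 in double KO vs WT and 7 to 13 in double KO vs Blm KO. Genes called alike ranged from 6 to 16 in Blm KO and double KO, 0 to 10 in Recql KO and double KO and 2 to 18 in Blm KO and Recql KO. The Blm log2 fold change in double KO vs WT ranged from -2.12 to -1.72, losing its call without WT replicate 1 (-1.87) and double KO replicate 1 (-1.94). For Recql it ranged from -0.35 to 0.12 (double KO vs WT), -0.047 to 0.42 (vs Blm KO) and -0.22 to 0.25 (vs Recql KO), for Cdkn2a in double KO vs Blm KO from -0.55 to 0.0016 and for the Trp53 interaction from -0.027 to 0.071. The camera adjusted p ranged, with a change of direction in 1 of 6 fits each, from 2.42e-25 to 0.73 for cholesterol biosynthesis and 1.5e-07 to 0.282 for glycolysis in double KO vs WT, and from 2.89e-08 to 0.457 for cholesterol biosynthesis and 3.35e-12 to 0.69 for interferon-stimulated genes in double KO vs Blm KO.

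With DESeq2, changed genes were 947 (Blm KO vs WT), 337 (double KO vs WT), 1404 (double KO vs Blm KO) and 2616 (interaction), and genes called alike were 98, 158 and 221. With fits on the groups compared alone, edgeR called 0 genes in double KO vs WT (1243 at an unadjusted p under 0.05) and 8 in double KO vs Blm KO, genes called alike were 0, 0 and 42, and Blm changed by -0.41 in Recql KO (adjusted p = 0.0242) and -1.92 in double KO (0.0661). With no filter on low counts, genes called alike in Blm KO and Recql KO were 10. With an estimated correlation, camera called 0, 1, 0, 0, 1 and 1 lists in the 6 comparisons in the order of the counts. In that order fry called 1 in Blm KO vs WT, 17 in Recql KO vs WT and 2 in double KO vs WT. It called 0 in double KO vs Blm KO, 14 in double KO vs Recql KO and 11 in the interaction.

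With the Y-linked level as a covariate, changed genes were 43 (Blm KO vs WT), 45 (double KO vs WT) and 829 (interaction), and Cdkn2a reversed to -0.031 in double KO vs WT. With only the libraries high in Y-linked transcripts, where a lone library was assumed to vary like the other groups, changed genes were 2 (Blm KO vs WT), 1128 (Recql KO vs WT) and 3 (double KO vs WT). Blm then changed by -1.87 in Blm KO and -1.58 in double KO without a call, Recql by 0.35 in double KO, Cdkn1a by -0.031 and Cdkn2a by -0.13 in Blm KO, and Cdkn2a by -0.20 in double KO. With only the libraries low in them, 31 genes changed in double KO vs Blm KO, and Recql changed by -0.083 there and -0.33 in double KO vs Recql KO.

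Libraries with the same replicate number did not deviate together, with correlations of -0.17 to 0.23 over 18 pairs, 5 of them over 0.1, and 4 of 12 libraries correlating best with their own number, so the numbers were not taken as pairs. With the replicate block, 50 genes changed in double KO vs WT and 762 in double KO vs Blm KO, and 19 were called alike in Recql KO and double KO.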

Other observations

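The tests of genes near Blm, of neighbouring genes and of the mixed-sex library were chosen after the results were seen, and the rule for the correlation near Recql was changed after its value was seen.

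In double KO against Recql KO, p53 targets had 0 of 29 genes higher and 9 lower, or 0 and 10 adjusted over the list alone (camera adjusted p = 0.000286, adjusted p = 0.48 with an estimated correlation). Glycolysis and hypoxia genes had 4 of 22 lower by either adjustment (camera adjusted p = 0.00868, adjusted p = 0.697 with an estimated correlation, and 0.0611 and 0.189 without Recql KO replicate 3 and double KO replicate 1), while cholesterol biosynthesis genes had 6 of 24 higher by either adjustment (camera adjusted p = 0.00339, adjusted p = 0.697 with an estimated correlation, and 0.363 without double KO replicate 2). Myofibroblast and smooth muscle genes had 5 of 14 higher by either adjustment (camera adjusted p = 0.00472, adjusted p = 0.547 with an estimated correlation), and mesothelial markers had 6 of 14 higher, among them Msln at 24.1-fold (camera adjusted p = 0.0109, adjusted p = 0.48 with an estimated correlation). In the interaction, endothelial markers had 4 of 10 positive, or 5 adjusted over the list alone (camera adjusted p = 0.000843, adjusted p = 0.138 with an estimated correlation), and epithelial markers 5 of 12, or 6 adjusted over the list alone (camera adjusted p = 0.000332, adjusted p = 0.312 with an estimated correlation).

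Genes called in Blm KO vs WT lay more often near Blm, for which a block of another strain's sequence may be a candidate explanation, and next to each other. Within 20 Mb of Blm 6 of 193 genes were called against 104 of 14615 elsewhere, an odds ratio of 4.48 (95% interval 1.59 to 10.3, 2-sided Fisher's exact p = 0.00317, BH-adjusted 0.0158 over 10 tests), among them Hddc3, Fam154b and Ngrn, the last 2 outside the fixed rule and chosen after their values were seen. In double KO vs WT 3 of 193 genes near Blm were called, an odds ratio of 16.5 (3.01 to 59.5, BH-adjusted Fisher's exact p = 0.013). In double KO vs Recql KO, where Blm also differs, 58 of 193 were called, an odds ratio of 1.31 (0.942 to 1.8, BH-adjusted 0.187). Fisher's exact test takes genes as independent, whereas calls in Blm KO vs WT lay next to each other. Its p-values may therefore be too small and its intervals too narrow. The counts near Blm were not compared with those in other windows. Of 110 called genes with a position in Blm KO vs WT, 27 had a called neighbour against a median of 2 and a maximum of 12 in 10000 random placements (permutation p = 1e-04, the smallest they can give). Neighbours were also called more often than in any placement in Recql KO vs WT (2452 of 4432, median 2252), double KO vs Blm KO (37 of 290, median 11) and double KO vs Recql KO (1755 of 3671, median 1591; permutation p = 1e-04 for each), and in double KO vs WT 0 of 17 had a called neighbour (permutation p = 1). An excess of called neighbours was thus not particular to Blm KO vs WT, but relative to the random median it was largest there. Blocks of another strain's sequence, coregulated neighbours or read-sharing neighbours may each produce it, and these were not told apart. Near Recql, 8 of 181 genes were called in double KO vs Blm KO, an odds ratio of 2.35 (0.99 to 4.8). Its 2-sided Fisher's exact p was 0.0263, BH-adjusted 0.0658, which misses 0.05 after adjustment. In double KO vs WT 2 of 181 were called there, an odds ratio of 10.9 (1.2 to 47.3, BH-adjusted Fisher's exact p = 0.0597). Against these stood 55 of 181 and an odds ratio of 1.02 (0.729 to 1.42) in Recql KO vs WT. Whether the libraries labelled Recql KO carry the segment of double KO stays open, since their changes against WT correlated across those 181 genes with a Spearman coefficient of 0.156, against a median of 0.214 and an SD of 0.0945 in 72 other windows, and a rule that first asked for any value under the median was changed to ask for more than 1 SD under it.

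The library labelled Recql KO replicate 2 held 310 CPM of Xist beside Y-linked transcripts at 10.5% to 14.5% of the mean of the libraries high in them. These shares differed by a factor of 1.38 between the 4 Y-linked genes, which is in line with RNA of cells of both sexes in 1 library. No biological explanation was tested for this pattern.

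Each comparison of 3 libraries with 3 has 10 divisions, too few for a share under 0.05. Counts of changed genes for the real division and the highest other were 112 and 1 (Blm KO vs WT), 4444 and 1 (Recql KO vs WT), 18 and 2 (double KO vs WT), 291 and 0 (double KO vs Blm KO) and 3681 and 0 (double KO vs Recql KO), with 1 division of 10 reaching the real count in each. Counts of called lists were 14 and 18, 16 and 14, 14 and 16, 12 and 15, and 17 and 17, with 4, 1, 3, 6 and 2 divisions reaching the real count.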
